A study of Mus musculus with 24 samples.

How the data were processed

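RNA was measured by sequencing in primary neurosphere cultures, floating aggregates of neural stem and progenitor cells, grown from mouse cerebral cortex or hypothalamus dissected at embryonic day 14.5. Per the labels' protocols, cultures at passage 3 received 100 nM dexamethasone, a synthetic glucocorticoid, or the same volume of ethanol for 4 hours, total RNA was extracted with Trizol, and libraries were made with a stranded total RNA kit. The labels placed the 24 samples in 8 groups of 3 biological replicates, by region, sex and treatment. They did not say whether a replicate was 1 embryo, litter or pool. Every sample was run on 2 lanes, which the deposited tables held as 1 column per sample.

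The submitters' processing notes named TopHat2 (versions 2.0.13 and 2.0.9), HTSeq and the genome build GRCm38. Which version served which libraries, the gene annotation and the strand setting of the counting were not given in the sources used here. Reads of genes that overlap, on either strand, and of near-identical copies such as Hspa1a and Hspa1b or the histone genes could therefore not be assigned with certainty. The authors deposited 4 tables, 1 for each region and sex, with the same 38924 gene entries. Per sample they deposited a normalized signal, reads per gene divided by a scaled library size, in reads per M reads (RPM). They also deposited log2 fold changes of dexamethasone over vehicle and p-values with their adjustment; per the file headers the fold ratio came from edgeR, and the test was not named.

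The deposited signal values of each library were whole multiples of what 1 read was worth: within a tolerance of 0.01 read, 100% of the values came out whole. Reads were recovered in this way, and they gave 16.39 to 20.94 M reads in genes per cortex library and 16.04 to 25.49 M per hypothalamus library. The hypothalamus scaling differed by at most 0.015% from edgeR's TMM factors over the 12 hypothalamus libraries. The cortex scaling differed by up to 4.13% from TMM over the 12 cortex libraries and its factors did not multiply to 1, and how it was made is not given in the sources used here. Gene symbols of 27 entries had been turned into dates. Of these, 4 entries shared 2 names and were left out, and the others, 0.259% to 0.363% of the reads of a library, were kept as 38920 genes in all but never named. No per-sample column was left unused (0 columns).

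Because the unit was a normalized signal, each comparison was tested with limma 3.58.1 (moderated statistics with a trend, R 4.3.3) on log2(value + 1), for genes at 1 RPM or more in at least 3 of the 6 libraries, 3 replicates against 3, with no block and Benjamini-Hochberg adjusted p under 0.05. Fold changes are on this log2(value + 1) scale, which understates the change of genes with low levels. Errors of fold changes are standard errors, and errors of levels are SDs over 3 replicates. The p-values measure the spread between these replicates. The differences in response between sexes and between regions were tested as limma interaction terms. This had been planned only for tables that shared a normalization, which they did not across regions, so recovered reads were rescaled by TMM over the 12 libraries of each difference first. As an added check, edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0 (Wald test) were run on the recovered reads.

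The comparisons, their planned tests and alternatives, and 27 lists with 431 genes in all were chosen before the data were examined. The lists were glucocorticoid targets, immediate-early genes, heat-shock and endoplasmic reticulum stress genes, glycolysis and hypoxia genes, inflammatory genes, histone genes, MAP kinase feedback genes, cholesterol synthesis, lipid metabolism, cell cycle, cyclin-dependent kinase inhibitors, neural stem cell, neuronal, astrocyte, oligodendrocyte, steroid receptor, circadian, sex-chromosome, cortex identity, hypothalamus identity, Notch/Wnt/Hedgehog/BMP, matrix and adhesion, endothelial, microglia, mesenchymal, ependymal and choroid plexus, and erythroid genes. Results of some list members, and those that rest on them, are not reported here. For each list the members that passed the test over all genes were counted, then those that passed when p was adjusted over the list alone. Lists with at least 3 measured members were tested with limma's camera, which compares a list with the other genes, at a preset correlation of 0.01 and with an estimated correlation, adjusted over the 95 tests of lists and comparisons. Of 25 calls with the preset correlation, 0 held with the estimated one.

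Genes were named by a fixed rule. It took the 10 largest rises and 10 largest falls past the test with a mean of at least 50 normalized counts in each comparison, and, at the same floor in both groups, the 10 smallest adjusted p of each difference in response, or the 3 smallest p where none passed. It also took the genes called in all 4 comparisons, up to 20, the glucocorticoid target, steroid receptor and sex-chromosome lists, and members of the other lists as examples of their group. Xist and the Gfap levels of single libraries were described after their values had been seen. Positions came from a GENCODE annotation of GRCm38, which matched 94.4% of the 13798 tested symbols and 98.8% of the 401 named ones. Of 62 genes checked for overlap, 10 overlapped another gene on the same strand and 21 on the opposite strand.

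Whether equal replicate numbers paired the samples was decided from the correlation of the deviations of vehicle and dexamethasone libraries from their group means, across genes. It was 0.87, 0.82 and 0.49 in female cortex, 0.74, 0.61 and 0.75 in female hypothalamus and 0.77, 0.66 and 0.75 in male hypothalamus. All these pairs lay over 0.1, and there a fit with the replicate number as a block was placed beside the results it changed. In female cortex, vehicle replicates 2 and 3 also reached 0.49 and 0.46 with a dexamethasone library of another number. The limit alone thus did not set the pairs apart there, and replicate 3 matched its own number (0.49) only slightly better. In male cortex 1 of 3 pairs missed this limit, so the numbers were not taken as pairs, which does not show that the samples were unpaired. No pair of replicates differed by as little as sampling noise, since the chi-square per degree of freedom was at least 6.05 over the 24 pairs.

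The procedures were tested on simulated counts drawn from the means and library sizes of these samples, with 200 genes changed by known folds. Of 100 genes changed 2-fold, limma recovered 36% in female cortex, 96% in male cortex, 78% in female hypothalamus and 76% in male hypothalamus. Of 100 genes changed 4-fold it recovered 97%, 99%, 99% and 97% in the same order, with 6, 9, 9 and 9 false calls. For the differences in response, 94.5% (cortex, sexes), 89.5% (hypothalamus, sexes), 87.5% (females, regions) and 98.5% (males, regions) of 200 genes that differed 4-fold were recovered. Lists of random genes left unchanged passed camera in 2, 2, 1 and 3 of 100 draws. Each gene was drawn independently, so this could not check lists whose genes move together. Libraries were drawn independently as well, without deviations shared by libraries of the same replicate number. The recovered shares therefore do not carry over to cultures with such deviations.

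Alternatives that were tried were other thresholds and pseudocounts (0.1 and 5), no filter, a minimum log2 fold change of 0.58, the block, the named-symbol genes alone, each replicate and each library left out, other scalings, count tests, all 24 samples in 1 fit, and thinning of reads to the shallowest library. Levels set side by side across regions were computed from the recovered reads with 1 TMM scaling over the 24 libraries, and no test was made on them. The single-library levels of Gfap, Hspb1 and Xist also used this scaling. Other levels given beside a fold change within a comparison are the deposited values. These differ in RPM from the common scaling and are not comparable between regions.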

Results

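Gene expression was profiled by stranded total RNA sequencing in cultured embryonic mouse neural stem and progenitor cells, to compare the early response to the glucocorticoid dexamethasone between the sexes and between 2 brain regions. The 8 groups were female and male cortex and female and male hypothalamus cultures, each with dexamethasone (100 nM, 4 hours) and with ethanol vehicle, at n = 3 biological replicates. Cortex libraries held 16.39 to 20.94 M reads in genes and hypothalamus libraries 16.04 to 25.49 M. In hypothalamus, mitochondrial ribosomal RNA (mt-Rnr2) took 21.3% to 40% of these reads, against 1.09% to 2.67% in cortex. The entries Gm26924 and Lars2, treated here with mt-Rnr1 and mt-Rnr2 as ribosomal-RNA-like, took up to 10.7%, in vehicle replicate 3 of male hypothalamus. Reads outside these genes and mt-Rnr1 came to 16.03 to 20.61 M in cortex and 10.13 to 15.96 M in hypothalamus, where 12258 to 12496 genes reached 1 RPM, against 12808 to 13350 in cortex. Region and library composition thus differed together. In cortex, composition also moved with treatment: mt-Rnr2 took 1.71% to 2.67% of the reads in vehicle libraries and 1.09% to 1.96% in dexamethasone libraries, and 13179 to 13350 against 12808 to 13102 genes reached 1 RPM.

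All groups expressed the neural stem cell genes Nes, the intermediate filament nestin, and Sox2, a stem cell transcription factor. Vehicle group means of Nes lay between 633 and 902 RPM and those of Sox2 between 248 and 378 RPM. Lhx2, a homeobox gene of the developing cortex, stood at 28.4 ± 6.05 and 23.6 ± 5.46 RPM in female and male cortex vehicle cultures (SD, n = 3), against 2.7 ± 2.43 and 4.02 ± 3.08 RPM in hypothalamus. Other cortex identity genes went both ways. Emx2 was higher in cortex vehicle cultures (13.3 and 13.4 against 5.26 and 4.17 RPM). Pax6 was not (35 and 28.2 against 43 and 39.6 RPM), and Emx1 was near 0 in both regions. Six3, a homeobox gene of the ventral forebrain, was at 7.21 ± 6.22 and 6.01 ± 3.21 RPM in hypothalamus and 0.725 ± 0.796 and 1.65 ± 0.704 RPM in cortex, but only 0.175 RPM in the lowest female hypothalamus library. The hypothalamic progenitor genes Nkx2-1 and Rax were near 0 in both regions, at no more than 0.4 and 0.0633 RPM in any library. Hypothalamus cultures also held more RNA of the contractile gene Acta2 (49.8 ± 9.19 and 52.4 ± 25.2 RPM) than cortex cultures (1.56 ± 1.25 and 3.9 ± 0.846 RPM), and more of the endothelial receptor gene Flt1 (11.9 ± 10.1 and 16 ± 8.72 against 0.317 ± 0.097 and 1.27 ± 0.305 RPM). The Y-linked gene Ddx3y had group means of 66 to 106 RPM in males and stayed under 0.2 RPM in females (highest 0.19). Xist, the X-inactivation RNA, was at 371 RPM or more in females and at most 0.632 RPM in males, except in both libraries of male hypothalamus replicate 2 (32.3 RPM with vehicle, 38.1 RPM with dexamethasone).

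The first question was which genes responded to dexamethasone in female cortex cultures. Fam107a, an actin-associated stress-response gene (chromosome 14, 8296274 to 8318023, GRCm38, protein-coding), rose from 0.347 ± 0.313 to 141.5 ± 31.3 RPM (SD, n = 3), a log2 change of 6.73 ± 0.24 (SE, adjusted p = 0.000539). Cftr, a chloride channel gene, rose by 5.79 ± 0.18, from 27 reads over the vehicle libraries to 4685 over the treated ones. The transcription factor gene Zbtb16 (chromosome 9, 48654297 to 48836222) rose by 4.29 ± 0.21, and Fkbp5, which encodes a co-chaperone that limits glucocorticoid receptor activity (chromosome 17, 28399094 to 28517527), rose by 3.40 ± 0.18, from 31.9 ± 7.67 to 341.0 ± 21.2 RPM. In the other direction Atf3, a stress-induced transcription factor (chromosome 1, 191170296 to 191218039), fell from 106.9 ± 21.4 to 2.85 ± 0.84 RPM, a log2 change of -4.81 ± 0.22 (adjusted p = 0.00122). Fos, an immediate-early transcription factor (chromosome 12, 85473890 to 85477273), fell from 259.5 ± 90.7 to 27.1 ± 6.05 RPM, a change of -3.18 ± 0.28 (adjusted p = 0.00517).

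The other large rises in female cortex were of Hif3a (4.73 ± 0.24), a hypoxia-inducible factor subunit, Ptk2b (4.63 ± 0.29), a focal adhesion family kinase, the sulfotransferase gene Chst2 (3.15 ± 0.21), the lipid droplet gene Plin4 (3.07 ± 0.34), Ada, adenosine deaminase (3.02 ± 0.24), and the dynein gene Dnah9 (2.98 ± 0.26). Among the glucocorticoid targets 11 of 28 measured members rose, 1 fell and 16 did not pass, and 12 rose and 3 fell when p was adjusted over the list alone. Members that rose included Tsc22d3, which encodes the leucine zipper protein GILZ (2.38 ± 0.22), Klf9 (1.99 ± 0.13), Glul, glutamine synthetase (1.87 ± 0.33), and the clock gene Per1 (0.86 ± 0.16). Cebpb, a C/EBP transcription factor, fell (-1.18 ± 0.19). The list passed camera (median 0.80, adjusted p = 4.4e-06), with an adjusted p = 0.521 with an estimated correlation.

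Immediate-early genes fell in 17 of 20 cases in female cortex, and in 20 of 20 when adjusted over the list alone. Fosb (-4.14 ± 0.22), Klf4 (-3.98 ± 0.23), Junb (-3.56 ± 0.18) and Egr2 (adjusted p = 0.0229) were among them. Egr1 changed by -2.91 ± 0.63 without passing (adjusted p = 0.0593). The median was -2.83 (camera adjusted p = 9.58e-24, and adjusted p = 0.262 with an estimated correlation). Heat-shock and endoplasmic reticulum stress genes fell in 7 of 16 cases (9 adjusted over the list alone), among them the Hsp70 genes Hspa1b (-3.38 ± 0.24) and Hspa1a (-3.09 ± 0.31), which share reads, and Chac1 (-3.50 ± 0.26), Ddit3 (-2.50 ± 0.16) and Atf4 (-2.13 ± 0.16), genes of the integrated stress response. Their camera adjusted p = 1.99e-06 became an adjusted p = 0.521 with an estimated correlation. Gadd45b, a growth arrest and DNA damage gene (-3.37 ± 0.21), Maff, a small Maf transcription factor (-3.42 ± 0.34), and Tnfrsf12a, the TWEAK receptor (-3.23 ± 0.55), were also among the 10 largest falls. Of 12 inflammatory genes 3 fell (Cxcl10, Irf1 and Relb; 7 adjusted over the list alone), with a camera adjusted p = 0.00234, and adjusted p = 0.521 with an estimated correlation. Of 15 glycolysis and hypoxia genes 1 fell (Pfkfb3, -1.82 ± 0.18; 1 adjusted over the list alone), with a median of -0.63, a camera adjusted p = 0.000644, and adjusted p = 0.774 with an estimated correlation. Of 14 MAP kinase feedback genes 1 fell (Dusp5, -2.30 ± 0.29; 2 adjusted over the list alone), with a camera adjusted p = 0.0213 and adjusted p = 0.864 with an estimated correlation. None of the 22 histone genes passed in limma (0, also adjusted over the list alone, with 13 higher under the block). Their median was 0.32, with a camera adjusted p = 0.0428 and adjusted p = 0.898 with an estimated correlation.

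Among lists with no camera call in female cortex, 1 of 13 astrocyte genes rose (Glul; 2 adjusted over the list alone), and 9 rose under the block, where camera passed (adjusted p = 0.000125, against 0.0573 without the block). With the block the lists of oligodendrocyte genes (7 of 12 higher, adjusted p = 0.0153 against 0.329) and cholesterol synthesis genes (10 of 16 lower, adjusted p = 0.000511 against 0.125) passed as well. These block calls used the preset correlation. Levels of such glial genes differed widely between these cultures: Gfap, the astrocyte filament gene, was at 3.24 and 6.64 RPM (vehicle, dexamethasone) in replicate 1, at 307 and 449 RPM in replicate 2 and at 137 and 207 RPM in replicate 3. Gfap ranged from 3.15 to 11.7 RPM in the male cortex libraries.

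In female cortex limma called 588 of 13314 genes, 186 higher and 402 lower, with 2848 at an unadjusted p under 0.05 (666 by chance), and edgeR called 556. The groups did not overlap for 28.6% of the genes, against 10% by chance. With the replicate number as a block, 5068 genes passed (2648 higher, 2420 lower), among them all 588. The authors' deposited table listed 2076 genes at an adjusted p under 0.05 in female cortex, 585 of them among the 588 and in the same direction. The count without the block moved with each replicate left out. Deviations from the group means were widest in replicate 1 (SD across genes 0.393 with vehicle, 0.384 with dexamethasone). They were narrowest in replicate 3 (0.172 and 0.164). The fits without replicate 2 or 3 kept replicate 1, so their low counts do not show that the response rested on replicates 2 and 3. Without replicate 3 limma called 0 genes (1069 at an unadjusted p under 0.05), without replicate 2 it called 2 and without replicate 1 it called 1634. Replicate 1 still responded, with Fam107a at 0.256 and 116 RPM and Atf3 at 95.6 and 2.11 RPM (vehicle, dexamethasone, 1 scaling over 24 libraries). Leaving out any 1 of the 6 libraries gave 56 to 348.

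**Figure D1:**
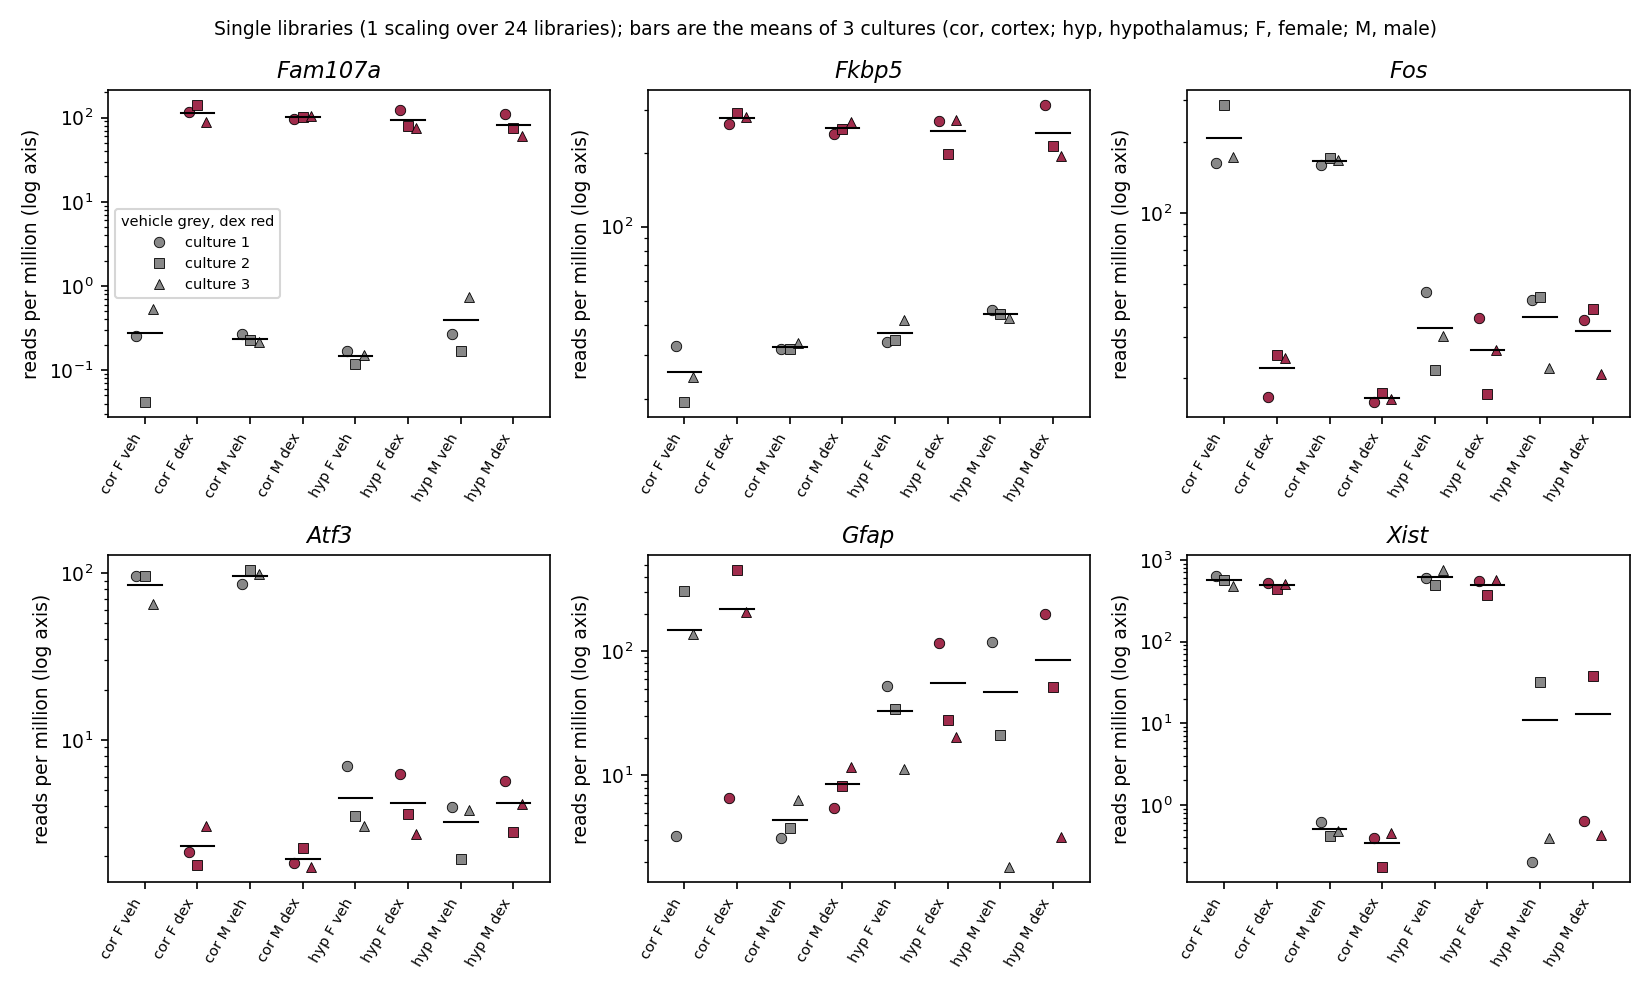
Levels of 6 genes in the 24 single libraries in RPM (log axis), with vehicle in grey, dexamethasone in red, marker shapes for the replicate number and bars for group means of 3 replicates. Fam107a and Fkbp5 were higher with dexamethasone in all 4 comparisons, Fos and Atf3 lay far lower with dexamethasone in cortex, Gfap differed between replicates, and Xist was at 32.3 and 38.1 RPM in male hypothalamus replicate 2.

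The same question was asked of male cortex cultures. Fam107a rose from 0.292 ± 0.033 to 125.9 ± 5.15 RPM, a log2 change of 6.62 ± 0.08 (SE, n = 3, adjusted p = 4.01e-11). Cftr (5.54 ± 0.13), Hif3a (4.63 ± 0.13), Ptk2b (4.26 ± 0.26) and Zbtb16 (3.73 ± 0.11) followed, and Fkbp5 rose from 39.8 ± 1.18 to 311.8 ± 17.2 RPM (2.94 ± 0.06). The calcium-activated potassium channel gene Kcnn2 (3.17 ± 0.12), the lipogenesis-associated gene Thrsp (3.00 ± 0.23), the cytoskeletal adaptor gene Kank1 (2.96 ± 0.16) and the lysolipid transporter gene Mfsd2a (2.93 ± 0.12) completed the 10 largest rises. Atf3 fell from 118.4 ± 10.9 to 2.38 ± 0.32 RPM (-5.14 ± 0.10, adjusted p = 5.07e-10) and Fos from 204.0 ± 5.41 to 20.5 ± 0.836 RPM (-3.26 ± 0.06). The other large falls were of Fosb (-4.50 ± 0.13), Klf4 (-4.02 ± 0.15), Hspa1a (-3.67 ± 0.25), Fosl2 (-3.65 ± 0.20), Gadd45b (-3.60 ± 0.13), Hspa1b (-3.56 ± 0.24), Junb (-3.32 ± 0.09) and Srxn1, an antioxidant gene (-3.24 ± 0.17).

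Of 28 measured glucocorticoid targets in male cortex 17 rose and 5 fell, and the counts were 17 and 5 adjusted over the list alone. Risers included Klf9 (2.14 ± 0.06), Tsc22d3 (2.11 ± 0.11), Glul (1.86 ± 0.05), the metabolic kinase gene Pdk4 (1.67) and Per1 (1.00). The members that fell were Sgk1, a serum- and glucocorticoid-regulated kinase (-1.62 ± 0.11), Dusp1, a phosphatase that limits MAP kinases (-1.37 ± 0.06), Cebpb (-1.11), Cdkn1a, a cyclin-dependent kinase inhibitor (-1.08), and Arrdc2 (-0.51 ± 0.13). Camera gave an adjusted p = 0.00127, and an adjusted p = 0.664 with an estimated correlation. The glucocorticoid receptor gene Nr3c1 itself fell by 0.31 ± 0.08 on the log2 scale (adjusted p = 0.00936). Of the same steroid receptor list Esr1, Hsp90aa1 and Fkbp4 fell and Ncoa1, Ncor1 and Cav1 rose, and the list did not pass camera (adjusted p = 0.242).

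All 20 immediate-early genes fell in male cortex (median -2.60, camera adjusted p = 8.31e-22, and adjusted p = 0.204 with an estimated correlation), and all 20 did adjusted over the list alone. Heat-shock and endoplasmic reticulum stress genes fell in 11 of 16 cases (11 adjusted over the list alone; adjusted p = 1.16e-06, and adjusted p = 0.664 with an estimated correlation). Glycolysis and hypoxia genes fell in 10 of 15 cases (11 adjusted over the list alone), among them Vegfa (-1.25 ± 0.26), the glucose transporter gene Slc2a1 (-1.04 ± 0.18) and hexokinase 2 (Hk2, -0.97 ± 0.16), with a camera adjusted p = 0.000644 and adjusted p = 0.821 with an estimated correlation. Of 13 inflammatory genes 8 fell, among them Ptgs2, cyclooxygenase-2 (-2.28 ± 0.19), Lif (-2.25 ± 0.16) and Icam1 (-1.98 ± 0.18), while Nfkb1 and Vcam1 rose (2 higher and 9 lower adjusted over the list alone). Camera gave an adjusted p = 0.0032, and an adjusted p = 0.637 with an estimated correlation. Of 16 cholesterol synthesis and uptake genes 10 fell and Mvk rose (adjusted over the list alone, also 10 and 1), with a camera adjusted p = 0.00234 and adjusted p = 0.664 with an estimated correlation.

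Histone genes rose in 22 of 22 cases in male cortex (22 adjusted over the list alone), with a median of 0.69, and linker histone gene Hist1h1b rose by 1.26 ± 0.06, from 196.3 ± 14.8 to 470.8 ± 14.5 RPM. These genes are near-identical copies, and how reads were split between them is not given in the sources used here. Camera gave an adjusted p = 9.27e-10, and an adjusted p = 0.664 with an estimated correlation. Astrocyte genes rose in 9 of 13 cases (9 adjusted over the list alone), among them the gap junction gene Gjb6 (2.04 ± 0.29), Gfap (0.83 ± 0.26) and the water channel gene Aqp4 (0.74 ± 0.22), with a camera adjusted p = 0.0111 and adjusted p = 0.664 with an estimated correlation. Oligodendrocyte lineage genes rose in 9 of 11 cases (9 higher and 1 lower adjusted over the list alone), among them Gpr17 (1.17 ± 0.20), Olig1 (0.56) and Olig2 (0.50), with a camera adjusted p = 0.0328 and adjusted p = 0.78 with an estimated correlation. The lists of neural stem cell genes (7 of 20 higher, such as the Notch target Hes5 at 0.84 ± 0.06, and 7 lower, such as Sox9 at -1.16 ± 0.09), cell cycle genes (12 higher, such as Top2a at 0.52, and 5 lower of 32), Notch, Wnt, Hedgehog and BMP genes (12 higher and 7 lower of 23) and MAP kinase feedback genes (4 higher and 7 lower of 14) moved in both directions without a camera call.

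In male cortex limma called 6279 of 13205 genes, 3520 higher and 2759 lower, with 7188 at an unadjusted p under 0.05 (660 by chance). edgeR called 6341, 5752 of them shared, with 3020 higher and 3321 lower. The groups did not overlap for 56.9% of the genes, against 10% by chance. Most of the calls were small: 1794 had an absolute log2 change of at least 0.58, 631 higher and 1163 lower. The authors' deposited table listed 2334 genes for male cortex, 1988 of them called here in the same direction.

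**Figure D2:**
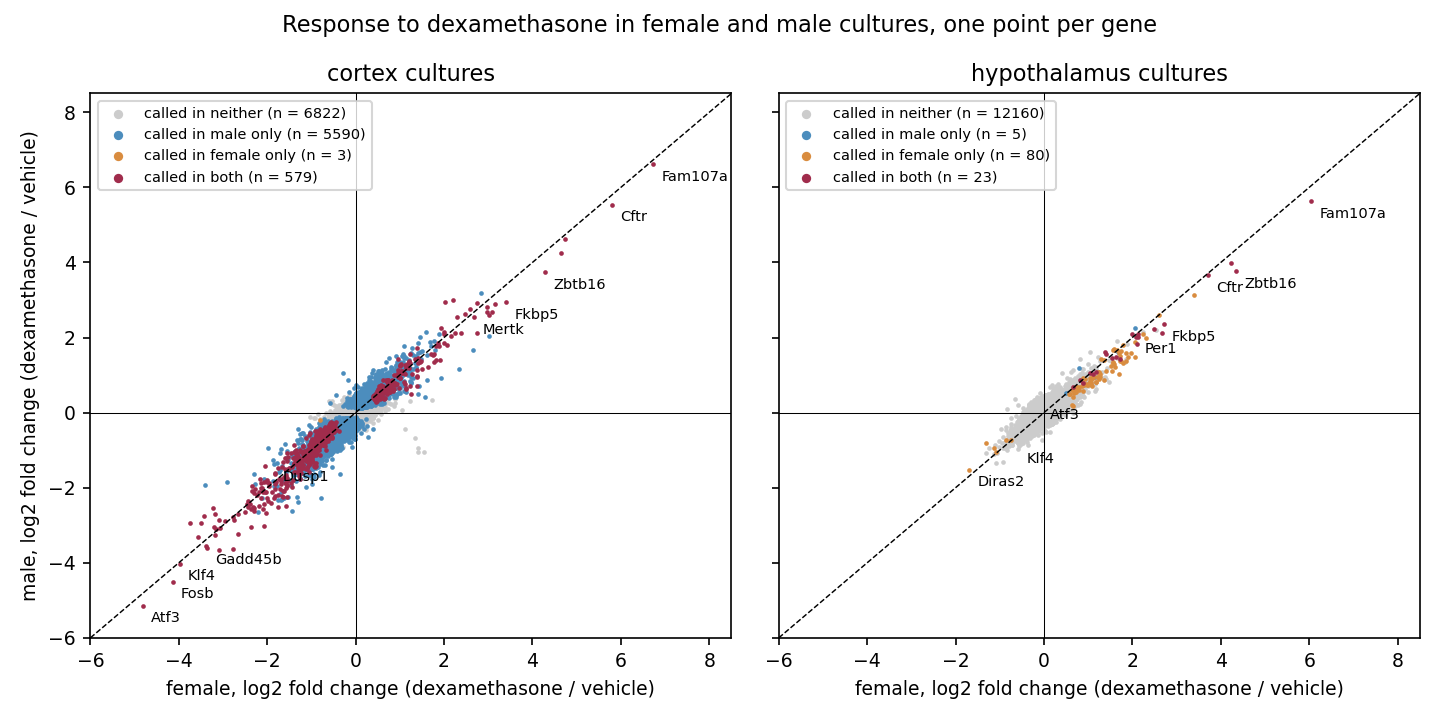
Log2 fold change of each gene (dexamethasone over vehicle) in female cultures (x axis) and male cultures (y axis), with colours for the comparisons that called it and the dashed line where both are equal. Across genes r was 0.929 in cortex (12994 genes) and 0.874 in hypothalamus (12268 genes).

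Whether the response differed by sex in cortex was tested with the sex-by-treatment interaction over 12 libraries. No gene passed: limma called 0 of 13680, with 169 at an unadjusted p under 0.05 where chance alone would give 684, in a fit that leaves out the culture number, and edgeR called 0, with 210 of 14851 unadjusted. Among genes with 50 normalized counts or more, the 3 with the smallest p were Adc (male minus female -0.56 ± 0.14), Mum1l1 (-0.55 ± 0.15) and 1500012F01Rik (-0.46 ± 0.13), each with an adjusted p of 1. Across the 6172 genes called in either sex, 98.3% changed in the same direction and the slope of male on female log2 changes was 1.02 (r = 0.957 across genes, which are not independent replicates). Of the 186 and 402 genes called higher and lower in females, 184 and 398 were tested in both sexes, and 184 and 395 of these were called in the same direction in males (49.6 and 81.6 for independent lists). The median SE of a difference was 0.206, so differences between the sexes were not excluded. Of simulated 4-fold differences 94.5% were recovered, but the simulation held no deviations shared by libraries of 1 culture. The power in the real cultures was therefore not measured. As a list, histone genes differed between sexes (median 0.33 higher in males, camera adjusted p = 2.53e-08), with an adjusted p = 0.714 with an estimated correlation and 0 members called. MAP kinase feedback genes differed by 0.45 (adjusted p = 0.00614, and adjusted p = 0.764 with an estimated correlation), Notch, Wnt, Hedgehog and BMP genes by 0.04 (adjusted p = 0.0109, and adjusted p = 0.16 with an estimated correlation) and neural stem cell genes by 0.08 (adjusted p = 0.0387, and adjusted p = 0.586 with an estimated correlation), with 0 members called. Without replicate 1 of each sex and treatment 27 genes passed.

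In female hypothalamus cultures glucocorticoid-induced genes rose, and in the fit without the block few genes fell. Fam107a rose from 0.116 ± 0.021 to 74.1 ± 19.9 RPM (SD, n = 3), a log2 change of 6.04 ± 0.19 (adjusted p = 3.7e-05). Zbtb16 (4.33 ± 0.21), Hif3a (4.23 ± 0.15), Cftr (3.70 ± 0.31), Ptk2b (3.39 ± 0.17), Ada (2.66 ± 0.18), Tsc22d3 (2.60 ± 0.20), Mfsd2a (2.48 ± 0.29) and Gjb6 (2.32 ± 0.27) followed, and Fkbp5 rose from 29.2 ± 3.36 to 197.2 ± 29.4 RPM (2.71 ± 0.14). Klf9 (chromosome 19, 23141226 to 23168134) rose by 2.12 ± 0.11 and Per1 by 2.09 ± 0.13. The 6 genes that fell in this fit were the Ras-family gene Diras2 (chromosome 13, 52504380 to 52531279; -1.69 ± 0.26), the potassium leak channel gene Kcnk3 (-1.31 ± 0.20), the phosphodiesterase genes Pde1b (from 151 to 68.8 RPM) and Pde3a (adjusted p = 0.0349), the GTPase gene Arl4a (-0.85 ± 0.13) and the kinase gene Hunk (-0.75 ± 0.12). Atf3, at 3.57 ± 1.70 RPM with vehicle and 3.36 ± 1.42 RPM with dexamethasone, did not pass (-0.06 ± 0.31, adjusted p = 0.971).

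Of 29 measured glucocorticoid targets in female hypothalamus 12 rose and 0 fell in limma (25 and 0 under the block), and 23 rose and 0 fell when adjusted over the list alone. Besides those above they included Errfi1, an inhibitor of the EGF receptor (1.72 ± 0.17), Bcl6 (1.52 ± 0.16), Nfkbia, the inhibitor of NF-kappaB (1.25 ± 0.17), and Arrdc2 (1.25 ± 0.16). The median was 1.27 (camera adjusted p = 7.18e-32, and adjusted p = 0.15 with an estimated correlation). None of 21 histone genes passed alone (0 over all genes in limma, 16 under the block, 18 adjusted over the list alone), with a median of 0.48, a camera adjusted p = 1.3e-17 and adjusted p = 0.521 with an estimated correlation. Immediate-early genes did not pass alone either (0 of 18, also adjusted over the list alone; 1 higher and 7 lower under the block). Their median was -0.33, with a camera adjusted p = 0.000467 and adjusted p = 0.664 with an estimated correlation. Camera also called the neural stem cell list lower (median -0.18, adjusted p = 0.00519) and the cell cycle list higher (median 0.11, adjusted p = 0.0213), with 0 of 20 and 0 of 32 members called by limma, 0 higher and 1 lower and 0 adjusted over the list alone, and adjusted p = 0.59 and adjusted p = 0.877 with an estimated correlation. Heat-shock genes (0 of 15 called, 1 adjusted over the list alone, adjusted p = 0.46) and inflammatory genes (0 of 10, adjusted p = 0.46) had no call. Hspb1, a small heat-shock gene, was at 3.26 to 16.1 RPM with dexamethasone and at 0 to 0.617 RPM with vehicle. Over all genes its log2 change of 2.53 ± 0.45 passed under the block but not without it (adjusted p = 0.0631).

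In female hypothalamus limma called 105 of 12491 genes, 99 higher and 6 lower, with 1113 at an unadjusted p under 0.05 (625 by chance), and edgeR called 108. The groups did not overlap for 15.2% of the genes, against 10% by chance. With the replicate number as a block 892 passed, 529 higher and 363 lower, among them all 105. The authors' deposited table listed 189 genes for female hypothalamus, 100 of them called here in the same direction. Leaving out replicate 1, 2 or 3 gave 17, 16 and 16 genes, and leaving out any 1 of the 6 libraries gave 32 to 69.

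In male hypothalamus cultures the rises were led by Fam107a, from 0.314 ± 0.240 to 65.1 ± 20.5 RPM (SD, n = 3), a log2 change of 5.62 ± 0.24 (adjusted p = 0.000963). Hif3a (3.98 ± 0.30), Zbtb16 (3.77 ± 0.30), Cftr (3.67 ± 0.20), Kcnn2 (2.25 ± 0.28), Mfsd2a (2.24 ± 0.28), Ada (2.13 ± 0.20), Map7d2 (2.08 ± 0.24) and Per1 (2.02 ± 0.23) also rose. Fkbp5 rose by 2.36 ± 0.17, to 191.0 ± 50.9 RPM, and Klf9 by 2.10 ± 0.11, from 18.9 ± 2.43 to 84.0 ± 2.55 RPM. The vascular peptide gene Adm rose by 0.94 ± 0.09, the 1 of 15 glycolysis and hypoxia genes called. Of 27 measured glucocorticoid targets 6 rose (Fkbp5, Hif3a, Klf9, Mertk, Per1 and Zbtb16) and 0 fell in limma (22 and 0 under the block), and 19 rose and 0 fell adjusted over the list alone. Tsc22d3 changed by 2.59 ± 0.34 without passing (adjusted p = 0.0522). The median was 1.25 (camera adjusted p = 4.79e-30, and adjusted p = 0.262 with an estimated correlation).

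None of 19 immediate-early genes passed in male hypothalamus (0 by limma, 2 lower adjusted over the list alone, 8 lower under the block). Their median was -0.40, with a camera adjusted p = 0.000834 and adjusted p = 0.664 with an estimated correlation. Klf4 changed by -0.90 ± 0.14 (adjusted p = 0.0801) and Atf3 by 0.28 ± 0.27 (adjusted p = 0.83). Camera also called the histone list higher (median 0.17, 0 of 21 members called, also adjusted over the list alone and under the block, adjusted p = 0.000729) and the neural stem cell list lower (median -0.16, 0 of 20 called, 1 lower adjusted over the list alone and 6 lower under the block, adjusted p = 0.012), with adjusted p = 0.821 and adjusted p = 0.664 with an estimated correlation. Sox9, a glial and stem cell transcription factor, changed by -0.85 ± 0.14. Over all genes it passed under the block but not without it (adjusted p = 0.085). The astrocyte list passed under the block (6 of 13 higher, adjusted p = 0.000121, against 0.0573 and 0 members without the block, 2 adjusted over the list alone). Gfap levels differed between these cultures, at 119 and 200 RPM (vehicle, dexamethasone) in replicate 1, 21.1 and 51.9 RPM in replicate 2 and 1.84 and 3.22 RPM in replicate 3. Hspb1 was at 2.48 to 13.8 RPM with dexamethasone and 0.113 to 0.402 RPM with vehicle. Its log2 change of 2.20 ± 0.47 did not pass over all genes (adjusted p = 0.2) without the block.

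In male hypothalamus limma called 28 of 12403 genes, 28 higher and 0 lower, with 960 at an unadjusted p under 0.05 (620 by chance), and edgeR called 25 higher and 0 lower. The groups did not overlap for 13.5% of the genes, against 10% by chance. Under the replicate block 1624 genes passed, 631 higher and 993 lower, among them all 28. The authors' deposited table listed 161 genes for male hypothalamus, 27 of them called here in the same direction. Without replicate 2, the culture with Xist RNA, limma called 0 genes (360 at an unadjusted p under 0.05). It called 7 without replicate 1 and 2 without replicate 3, and 7 to 18 without any 1 of the 6 libraries.

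The sex-by-treatment interaction in hypothalamus also gave no call. limma called 0 of 12843 genes, with 33 at an unadjusted p under 0.05 (281 under the block, also with 0 calls) where chance would give 642, and edgeR called 0, with 73 of 14352 unadjusted. Among genes with 50 normalized counts or more, the smallest p belonged to Dpm1 (male minus female 0.58 ± 0.19), which overlaps Gm20716 on the same strand, Nrbf2 (0.41 ± 0.14) and the histone gene Hist1h2bm (-0.48 ± 0.16), each with an adjusted p of 1. All 108 genes called in either sex changed in the same direction in both (100%), with a slope of 0.915 (r = 0.982 across genes). The median SE of a difference was 0.208, and 89.5% of simulated 4-fold differences were recovered, in a simulation without deviations shared by libraries of 1 culture. As lists, histone genes (median -0.32, male minus female) and cell cycle genes (-0.18) differed between sexes with camera adjusted p = 1.45e-19 and 4.6e-09, with adjusted p = 0.267 and adjusted p = 0.598 with an estimated correlation and 0 members called. The median histone difference was opposite in sign to that in cortex. This change of sign was not tested, and the histone call held with an estimated correlation in neither region. Cholesterol synthesis genes differed by -0.08 (adjusted p = 0.000838, and adjusted p = 0.561 with an estimated correlation). Under the block the astrocyte list passed as well (median 0.21, adjusted p = 4.07e-05 against 0.197), as did the ependymal (0.0136), MAP kinase feedback (0.0143), sex-chromosome (0.0143) and circadian lists (0.0381). With an estimated correlation and no block, camera gave an adjusted p of 0.863 (astrocyte), 0.586 (ependymal), 0.851 (MAP kinase feedback) and 0.442 (circadian).

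Genes shared by the 4 comparisons were counted next, since these share no libraries. Of 12001 genes tested in all 4, 19 were called in all 4 without the block, and all 19 were higher: Fam107a, Cftr, Hif3a, Zbtb16, Fkbp5, Mfsd2a, Ada, Mertk, Map7d2, Dnah9, Klf9, Cables1, Per1, Bcl2l1, Zfp189, Lgalsl, Ak3, Megf9 and Mbnl2. Bcl2l1, an anti-apoptotic gene, rose by 1.63 ± 0.08 in female and 1.49 ± 0.15 in male hypothalamus. Mertk, a receptor kinase for uptake of dying cells, rose by 2.12 ± 0.16 in female and 2.01 ± 0.24 in male hypothalamus. The RNA-binding gene Mbnl2 had the smallest change in male hypothalamus, 0.67 ± 0.08. Female cortex and female hypothalamus shared 47 higher genes, against 1.44 for independent lists, and male cortex and male hypothalamus shared 27, against 7.98. Female and male hypothalamus shared 23 of 97 and 28 higher genes, against 0.221. In 3 or more comparisons 50 genes were higher and 1 was lower. Without replicate 1, 2 or 3 of every group, limma called 6, 0 and 0 genes in all 4. Under the block the genes called in all 4 lay in both directions, though the male cortex numbers had not been taken as pairs. Genes called in 1 comparison that moved the same way at an unadjusted p under 0.05 in the others came to 258, 180 higher and 78 lower.

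**Figure D3:**
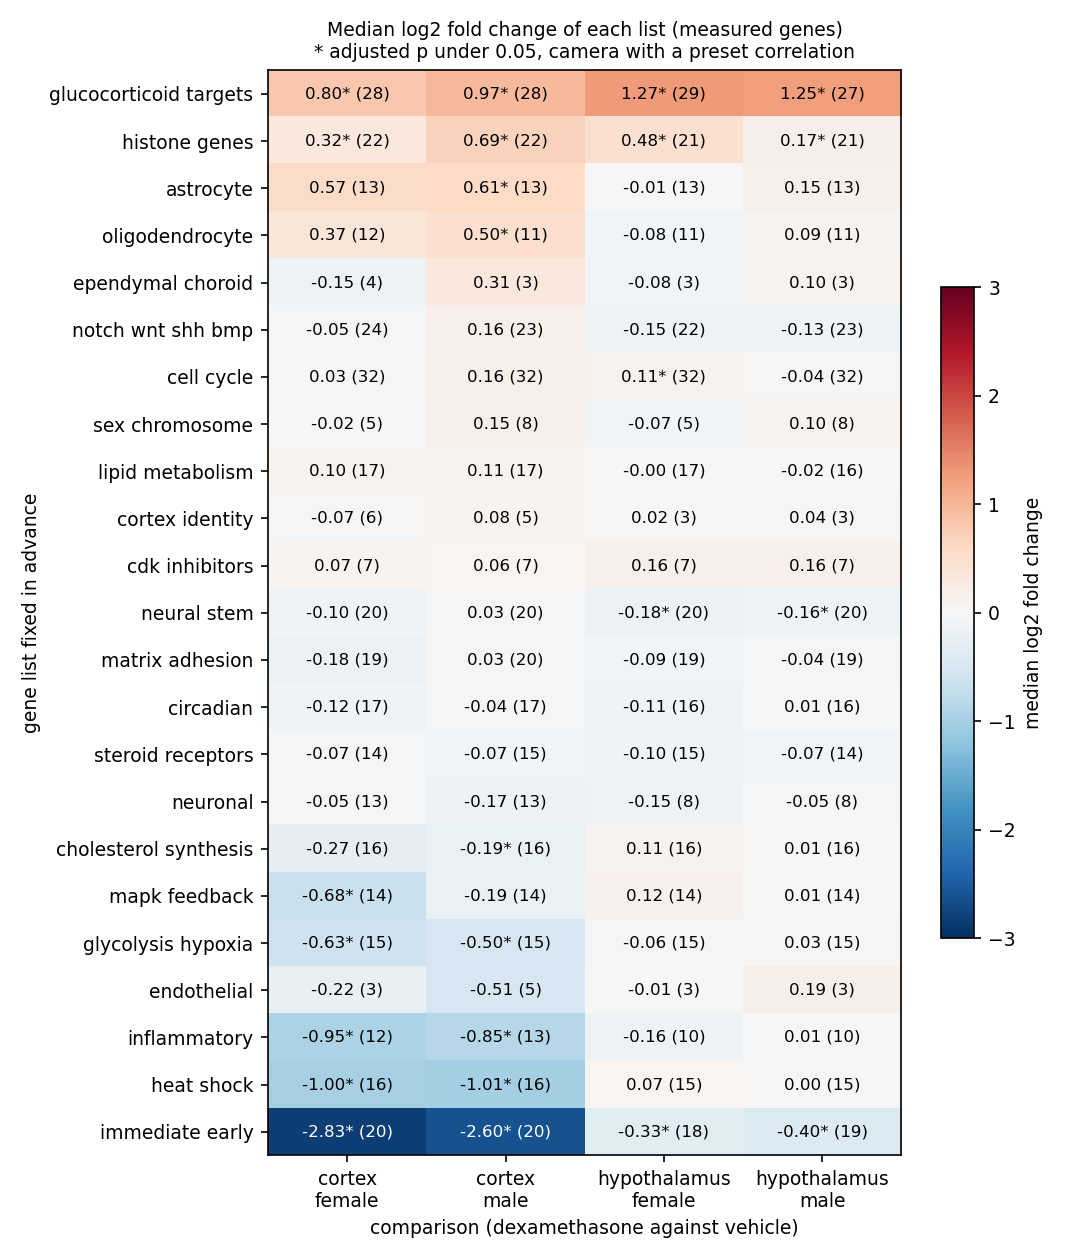
Median log2 fold change of each gene list fixed in advance (vertical axis) in the 4 comparisons (horizontal axis), with the number of measured genes in parentheses and a star where camera with the preset correlation gave an adjusted p under 0.05. Glucocorticoid targets were positive in all 4 columns (0.80 to 1.27), while immediate-early genes were at -2.83 and -2.60 in cortex and at -0.33 and -0.40 in hypothalamus.

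Whether the response differed by region was tested with the region-by-treatment interaction within each sex. In females 80 genes were lower and 14 higher in the difference (cortex minus hypothalamus). The smallest adjusted p belonged to Fosb (-3.69 ± 0.26, adjusted p = 0.000386), which lay below the floor of 50 normalized counts in hypothalamus. Among genes over this floor it belonged to Ppp1r15a, an inducible phosphatase subunit of the stress response (chromosome 7, 45522916 to 45526268), with a log2 change of -2.70 in cortex and -0.23 in hypothalamus and a difference of -2.47 ± 0.21 (adjusted p = 0.00104). Gadd45b (-3.49 ± 0.31), Atf3 (-4.62 ± 0.43) and Sesn2, a stress-responsive sestrin (-2.33 ± 0.23), followed, then the zinc exporter gene Slc30a1 (-1.98 ± 0.20), the phosphatase gene Ppm1d (-1.17 ± 0.12), Junb, Klf4 (-3.27 ± 0.34), Vasn (-1.28 ± 0.13) and Mafk (-1.80 ± 0.19), all at an adjusted p of 0.00161. Vasn shares a strand with the overlapping gene Dnaja3, and Sesn2 with Gm12981. In all 94 of 13582 genes passed, with 1660 at an unadjusted p under 0.05 (679 by chance). With the replicate block 2102 passed, among them all 94, and these were close to balanced (1123 higher, 979 lower). Without replicate 1 limma called 47 genes, and without replicate 2 or 3 it called 0 (808 and 785 at an unadjusted p under 0.05).

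In males 1103 of 13452 genes differed between regions, 495 higher and 608 lower in cortex minus hypothalamus, with 3118 at an unadjusted p under 0.05 (673 by chance). The balance turned with the threshold and the genes tested: at an adjusted p under 0.10 there were 922 higher and 869 lower, and among genes with 50 normalized counts or more 464 and 365. Maff (-2.80 ± 0.16), Phlda3, a p53 target gene (-1.93 ± 0.11), and Atf3 (-5.34 ± 0.32) had the smallest adjusted p among genes over the floor of 50 normalized counts, 8.59e-06 each, and Fosb, below it, had the same (-4.30 ± 0.24). Atf3 changed by -5.06 in cortex and by 0.28 in hypothalamus. Ppp1r15a (-3.001 ± 0.19), Slc30a1 (-1.95 ± 0.12), Sertad1 (-2.27 ± 0.15), Cited2 (-2.47 ± 0.18), Klf4 (-3.04 ± 0.23), Dusp5 (-2.47 ± 0.19) and the pro-apoptotic gene Bbc3 (-1.77 ± 0.14) followed. Leaving out replicate 1, 2 or 3 of each group gave 578, 100 and 229 genes.

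As a list, immediate-early genes differed between regions by a median of -2.29 in females (7 of 20 members called lower) and -2.31 in males (17 of 20), with camera adjusted p = 1e-28 and 1.76e-24, and adjusted p = 0.0504 with an estimated correlation in both. Heat-shock and endoplasmic reticulum stress genes differed by -1.44 (7 of 16) and -1.46 (11 of 16), with camera adjusted p = 1.39e-13 and 6.49e-13, and adjusted p = 0.143 and adjusted p = 0.16 with an estimated correlation. Glucocorticoid targets differed less, by -0.22 (4 of 30) and -0.12 (8 of 28), with camera adjusted p = 0.00225 and 0.0109, and adjusted p = 0.561 and adjusted p = 0.714 with an estimated correlation. Some heat-shock and stress members called in at least 1 sex were low in hypothalamus vehicle cultures: Hspa1a (0.647 and 0.312 RPM, female and male) and Trib3 (1.51 and 1.42 RPM). A fall there could hardly show on the log2(value + 1) scale. Atf4, also called, stood at 129 and 160 RPM. Hspb1, called as well, rose in female hypothalamus (0.264 to 8.71 RPM) and did not fall in female cortex (0.817 to 1.01 RPM). In males histone genes were higher in the difference (median 0.57, 8 of 22 called, camera adjusted p = 1.31e-08, and adjusted p = 0.689 with an estimated correlation), as were cell cycle genes (0.15, 5 of 32, adjusted p = 0.00729, and adjusted p = 0.714 with an estimated correlation). Lists lower in the difference in both sexes were inflammatory genes (-0.89 and -0.62; 0 and 6 of 13 called; camera adjusted p = 7.85e-05 and 4.48e-06, and adjusted p = 0.0504 and adjusted p = 0.13 with an estimated correlation) and glycolysis and hypoxia genes (-0.68 and -0.58; 0 and 2 of 15; adjusted p = 0.0011 and 0.00136, and adjusted p = 0.714 and adjusted p = 0.717 with an estimated correlation). So were MAP kinase feedback genes (-0.74 and -0.10; 2 and 4 of 14; adjusted p = 7.2e-05 and 0.0493, and adjusted p = 0.714 with an estimated correlation in both) and cholesterol synthesis genes (-0.25 and -0.17; 0 and 4 of 16; adjusted p = 0.0172 and 0.00165, and adjusted p = 0.863 and adjusted p = 0.486 with an estimated correlation). Circadian genes were lower in females (-0.24, 1 of 17, adjusted p = 0.0273, and adjusted p = 0.561 with an estimated correlation), and in males 2 of 17 were called lower without a camera call (median -0.06, adjusted p = 0.0607). Under the block the female difference also held astrocyte (camera adjusted p = 0.00433) and oligodendrocyte genes (0.00572), both higher. Without the block these were 0.322 and 0.457, and 0.915 and 0.879 with an estimated correlation. The levels with vehicle, after 4 hours of ethanol, differed too. In vehicle cultures Atf3 stood at 85.4 ± 17.7 (female) and 96.3 ± 9.16 RPM (male) in cortex and at 4.5 ± 2.14 and 3.21 RPM (range 1.92 to 3.96) in hypothalamus. Fos stood at 206 ± 68.3 and 166 ± 5.02 RPM in cortex and 32.6 ± 12.5 and 36.4 ± 12.4 RPM in hypothalamus, and Junb at 74 ± 13.2 and 72.3 ± 3.74 against 7.15 ± 2.76 and 10.5 ± 2.9 RPM. Across genes the fold changes of the regions correlated with r = 0.478 in females and 0.516 in males, and of the genes called in either region 81.5% of 568 in females and 71.5% of 5792 in males had the same sign.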

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

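Among the tests of this part, the comparison of vehicle levels between regions was chosen only after the result was seen.

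The 20 results below stood out because the test of the difference in response between regions passed, and each value is cortex minus hypothalamus on the log2 scale. In females they were Ppp1r15a (-2.472), Gadd45b (-3.495), Atf3 (-4.625), Sesn2 (-2.329), Slc30a1 (-1.977), Ppm1d (-1.169), Junb (-3.345), Klf4 (-3.269), Vasn (-1.279) and Mafk (-1.798). In males they were Maff (-2.799), Phlda3 (-1.926), Atf3 (-5.343), Ppp1r15a (-3.001), Slc30a1 (-1.948), Sertad1 (-2.271), Cited2 (-2.466), Klf4 (-3.036), Dusp5 (-2.466) and Bbc3 (-1.768). No sample was tested as an outlier, since every group held 3.

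Over the 36 immediate-early, heat-shock and endoplasmic reticulum stress genes measured in both regions, the median difference was -1.88 in females and -1.85 in males. The tables argued against a trend with GC content and transcript length. With the trend removed the median difference was still -1.83 in the sex with the smaller one. They also argued against the reads of the 4 ribosomal-RNA-like entries and the scaling built on them, since without these entries it was -1.91. Their removal did not test other differences between libraries that go with the share of ribosomal RNA. What stays open is that the cortex vehicle cultures may have carried a stress or handling response that dexamethasone lowered: the 36 genes were higher in cortex than in hypothalamus with vehicle by a median of 1.57, in 31 of 36 cases, and with dexamethasone the median was -0.353. A culture state, a dissection or processing day and a difference between the regions themselves cannot be told apart here, because every cortex library also differed from every hypothalamus library in its share of ribosomal RNA. That the difference in response came from the regions themselves thus remained an untested hypothesis.

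In other assignments of the libraries to the regions within each treatment, the female difference was matched by 1 of 100, the real one (94 genes, highest other 2), and the male difference by 1 of 100, the real one (1103 genes, highest other 1). The region means of each gene had been removed first. None of the other reassignments drawn reached the counts without the block. They also broke the culture pairs, so the test could not decide whether chance gave these counts. For the hypothalamus sex difference the same procedure reached 86 calls where the real value was 0. The female count came to 0 without replicate 2 or 3.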

How the results depend on the processing

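Added after the data were seen were the edgeR, DESeq2 and all-sample fits, the TMM scalings within a comparison, the thinning, the block, omissions and edgeR fit of the overlap, and the block, estimated correlation and omissions of the lists. No called gene named here changed direction, and no list call became a call in the opposite direction, but balances of higher and lower genes did change. In male cortex (3520 higher, 2759 lower) edgeR gave 3020 and 3321, DESeq2 2756 and 2778, no filter 3250 and 3374, the minimum change 631 and 1163 and all samples in 1 fit 1209 and 1626. Under the block the majority turned in female cortex (2648 and 2420), male hypothalamus (631 and 993) and both region differences. The male region difference (495 and 608) also turned at an adjusted p under 0.10 (922 and 869), with adjustment over called genes (861 and 830) and at 50 or more counts (464 and 365). Of the counts under alternatives, 81 stayed within 1.5 times and 68 did not. The cause was not tested for those that moved, other than by the changed threshold, subset or number of samples itself.

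Calls at an adjusted p under 0.01 and 0.10 were 83 and 1286 in female cortex, 24 and 159 in female hypothalamus, 10 and 74 in male hypothalamus, 30 and 189 for the female and 400 and 1791 for the male region difference, and 7 and 39 for genes called in all 4. With an absolute log2 change of at least 0.58 male cortex gave 1794. Adjusting only over genes called in either comparison gave 406 and 1691 region differences in females and males. The block gave 5068, 892 and 1624 in the paired comparisons, 2102 for the female region difference (1123 higher, 979 lower) and 449 for the overlap (274 and 175). In male cortex, where pair 2 correlated less with its own number (0.021) than with another (0.034) and pairs 1 and 3 best with their own (0.36 and 0.39), it gave 6868, and 3517 for the male region difference (2057 higher, 1460 lower). For the cortex sex difference it gave 0 in limma, with 803 at an unadjusted p under 0.05 and a smallest adjusted p of 0.774. For that difference the lists of cell cycle (0.00411 against 0.222), neuronal (0.0116 against 0.227) and circadian genes (0.0192 against 0.086) passed camera under the block. With an estimated correlation and no block their camera adjusted p was 0.947, 0.586 and 0.714. In male cortex the MAP kinase feedback list passed camera under the block (adjusted p = 0.0421 against 0.0784), and in the male region difference the circadian list did (0.0164 against 0.0607).

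DESeq2 gave 1639, 291 and 223 in female cortex, female hypothalamus and male hypothalamus, and edgeR with all 24 samples 2612, 2835, 199 and 163 in female and male cortex and female and male hypothalamus. Thinning to 10.13 M reads outside the ribosomal-RNA-like entries changed depth, gene set and scaling together and gave 388 in female cortex. A relaxed overlap held 258 genes (180 higher, 78 lower), and list calls with an estimated correlation came to 0.

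Omitting replicates or single libraries gave 0 to 1634 in female cortex, where each omission moved the count (replicate 1 1634, 2 2, 3 0; vehicle libraries 1 to 3 221, 91 and 111; dexamethasone 348, 86 and 56), and 4440 to 5867 in male cortex. It gave 16 to 69 in female hypothalamus (replicates 17, 16 and 16; vehicle 32, 48 and 35; dexamethasone 38, 35 and 69) and 0 to 18 in male hypothalamus (replicates 7, 0 and 2; vehicle 13, 9 and 10; dexamethasone 18, 7 and 13). By replicate, the sex difference gave 0 to 27 in cortex (27 without replicate 1) and 0 in hypothalamus. The region difference gave 0 to 47 in females (47, 0 and 0) and 100 to 578 in males (578, 100 and 229). The overlap gave 0 to 6 (6, 0 and 0) and the lists 24 to 30. These fits used limma, and edgeR was not run on these subsets; unadjusted counts for the comparisons and female region differences that came to 0 stand in the report.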

Other observations

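Among the tests of this part, the block test of the female cortex count and both tests of Xist were chosen only after the results were seen.

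Lists that the report did not describe held few calls outside male cortex. Circadian genes passed in 4 of 17 cases in female cortex, where Npas2 (1.09) and Per1 rose and Bhlhe40 (-1.46) and the clock repressor gene Nr1d1 (-1.34) fell. In male cortex 3 of 17 rose, among them Per2 (from 18.8 ± 2.19 to 42.3 ± 3.52 RPM), and 5 fell, and in each hypothalamus comparison Per1 alone of 16 was called. Adjusted over the list alone, the circadian counts were 2 higher and 3 lower, 3 and 5, 2 and 0, and 2 and 0. Of 17 lipid metabolism genes 2 rose in female cortex (Lpin1 at 0.72 ± 0.13, and Plin4), 7 rose and 3 fell in male cortex, 1 rose in female hypothalamus (Plin4, 1.41 ± 0.23) and 0 of 16 passed in male hypothalamus (adjusted over the list alone, 3, 7 and 3, 2, and 0). Matrix and adhesion genes fell in 3 of 19 cases in female cortex (Adamts1, Thbs1 and Fn1), rose in 6 and fell in 7 of 20 in male cortex, and had 0 calls of 19 in each hypothalamus comparison (the same counts adjusted over the list alone). None of these lists passed camera in any of the 4 comparisons (lowest adjusted p = 0.0752, matrix genes in female hypothalamus).

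Of the microglia list only Cd68, a lysosomal gene, was measured, and it fell in female (-1.63 ± 0.26) and male cortex (-2.08), while the microglial gene Aif1 was at 0.237 RPM or less in every library. Endothelial genes fell in 1 of 3 cases in female cortex (Pecam1, -0.87) and in 4 of 5 in male cortex (Esam, Flt1, Kdr and Pecam1). Of the mesenchymal genes 2 of 3 fell in male cortex (Col1a1 and Foxc1), and of the ependymal and choroid plexus genes 1 of 3 rose there (Ccdc39). Neuronal genes rose in 1 of 13 cases (Map2) and fell in 5 (Neurod1, -0.90, among them) in male cortex. Of the cyclin-dependent kinase inhibitors 2 of 7 rose (Cdkn2c and Cdkn2d) and 2 fell (Cdkn1a and Cdkn2b) there. Of the sex-chromosome genes 2 of 8 rose (Eif2s3x and Kdm5d), of the cortex identity genes 2 of 5 rose (Emx2 and Pax6), and 0 of 2 hypothalamus identity genes passed. Apart from the genes named, limma called 0 members of the lists of this paragraph in the other 3 comparisons, and none passed camera where it was run (lowest adjusted p = 0.0904, endothelial genes in male cortex). Adjusted over the list alone, the counts given held, with 1 more lower cyclin-dependent kinase inhibitor in female cortex.

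In female cortex 0 of 24 Notch, Wnt, Hedgehog and BMP genes, 0 of 32 cell cycle genes and 0 of 20 neural stem cell genes passed (2 lower, 0 and 0 adjusted over the list alone; camera adjusted p = 0.46, 0.639 and 0.219). Steroid receptor genes passed in 0 of 15 and 0 of 14 cases in female and male hypothalamus (the same counts adjusted over the list alone; camera adjusted p = 0.542 and 0.279). In the hypothalamus comparisons 0 or 1 member passed of the lists of oligodendrocyte (Cspg4, 0.85 ± 0.12, in females), glycolysis and hypoxia (Adm in males), MAP kinase feedback (Errfi1 in females), cholesterol synthesis, and Notch, Wnt, Hedgehog and BMP genes, and none of these passed camera. Inflammatory and heat-shock genes in male hypothalamus had 0 of 10 and 0 of 15 calls (0 and 1 adjusted over the list alone; adjusted p = 0.971 and 0.46).

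Fewer genes were called in female than in male cortex by limma within each comparison (588 against 6279), while edgeR with all 24 samples in 1 fit gave 2612 against 2835 and the authors' deposited table listed 2076 against 2334. Depth was argued against, since with every cortex library thinned to 16.39 M reads male cortex still gave 6124 calls and female cortex 531. Smaller fold changes in females were argued against as the main reason, since over the genes called in males the female median was 0.884 of the male one, and 98.3% of the genes called in either sex changed in the same direction. Differences between cultures that both treatments share are a candidate explanation: with the replicate number as a block female cortex gave 5068 calls and male cortex 6868, and the culture deviations were wider in females, at 0.164 to 0.393 against 0.103 to 0.127. Sex as a biological reason was not tested apart from culture, and the difference in response itself gave 0 calls in limma (169 at an unadjusted p under 0.05) and 0 in edgeR.

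Xist in male hypothalamus replicate 2 averaged 6.39% of the female hypothalamus mean, from 574 and 658 reads. A female sample with a male label was argued against, since the Y-linked genes of its libraries stood at 0.844 or more of their mean in the other 4 male hypothalamus libraries. A small share of female cells or of female RNA may have been present, and the tables do not decide between these and Xist expression by male cells. No biological explanation was tested.

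In other splits of the 6 libraries of each comparison, 1 of 10, the real one, gave as many calls in female cortex (588, highest other 0), 1 of 10 in male cortex (6279, highest other 0), 1 of 10 in female hypothalamus (105, highest other 0) and 1 of 10 in male hypothalamus (28, highest other 0). These splits are too few for a share under 0.05. Where numbers pair the samples, 4 splits part all 3 pairs, and the 3 that are not the real one gave 0 calls. Every split but the real one mixed vehicle and dexamethasone libraries within both groups, and the treatment effect had not been removed. Their 0 calls therefore do not show what chance alone would give. For the differences between sexes the real value was 0, so 100 of 100 reassignments gave as many in cortex (highest other 0) and 100 of 100 in hypothalamus. There the highest other was 86, which may point to a structure of the samples, and its cause was not tested.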
